A study of Mus musculus with 45 samples.

How the data were processed

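RNA from whole ileum pieces, snap-frozen on dry ice per the labels, was measured on 45 microarrays, with 1 mouse per array and 5 mice in each of 9 groups. The mice were about 11 weeks old per the labels, were kept free of specific pathogens on chow, and the sex was not given. Per the labels, the target was prepared with a WT PLUS kit. Summary values were made in Affymetrix Expression Console and analysed in Transcriptome Analysis Console, per the submitters' processing notes, which name no versions. The summarization method was not given in the sources used here. The deposited values were log2 intensities, normalized by the authors; array medians lay between 6.36 and 6.44, single values between 1.36 and 13.41, and no 2 arrays were identical. For arrays, only their number limits the precision: 5 mice per group.

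The table held 22142 probes. Of these, 19527 were paired with 1 gene symbol, 0 with several and 2615 (11.8%) with none; there were 0 control probes. Symbols were matched to a mouse gene table of assembly GRCm38.p6 by gene number, which was used only for names and for which genes neighbour each other. Where several probes shared a gene (33 genes), the probe with the highest mean was kept, which left 19494 genes. Probes without a symbol were left out of the comparisons and counted separately. No filter on dim probes was applied.

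Groups followed the sample titles. In the group titled FADD IEC-KO CASP8 IEC-KO Mlkl-/- the genotype field gave CASP8 IEC-KO Mlkl-/- alone; the titles were used, and Fadd was measured as a check. In the names, fl/fl stands for floxed alleles without deletion and IEC-KO for deletion in intestinal epithelial cells. Titles carried numbers, either under 100 or 200 and over, whose meaning the labels do not state; they were treated as a possible batch. All triple mutants had numbers of 200 and over, and no FADD IEC-KO Mlkl-/- mouse did. Numbers under 100 mostly ran in blocks by genotype, such as 36 to 40 in CASP8 IEC-KO Mlkl-/- and 41 to 45 in FADD IEC-KO Mlkl-/-. The titles share no numbers that would pair mice across groups.

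Differential expression was tested with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 45 arrays (36 residual degrees of freedom), so that the groups shared an estimate of each gene's spread, and contrasts were tested with eBayes. P-values were adjusted by the Benjamini-Hochberg method over 19494 genes within each comparison, with calls at an adjusted p under 0.05; errors of log2 fold changes are standard errors from this fit. There were 16 comparisons and 2 interactions. P-values rest on the spread between mice pooled over all 9 groups, and the groups differed in spread. The score of FADD-loss genes described below had an SD of 0.72 in CASP8 IEC-KO and 0.10 in Casp8 fl/fl. Where the groups compared vary more than the others, standard errors and p-values can be too small. Comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

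Named genes were chosen by rule: the 5 targeted genes; in the first 8 comparisons the 6 largest rises and 6 largest falls in log2 fold change among called genes with complete separation of the mice; in the others the 3 largest rises and 3 largest falls among called genes; and, for each list described, up to 3 called members with the largest absolute change, or the member with the highest mean where none was called. Genes named outside the rule are said to be so. Predicted genes known only by clone or locus names were not printed.

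Gene lists for cell types and responses (48 lists, 699 entries, 621 measured) were tested with camera at a preset correlation of 0.01, two-sided, over the 47 lists with at least 3 measured genes, adjusted within each comparison. Camera with an estimated correlation and fry were alternatives. Fry tests whether a set's genes move, on balance, in a single direction and does not compare the set with other genes. Defa30 entered both Paneth cell lists, because a locus name in the second list is now Defa30. The report describes some of the called lists and not all; which ones was decided after the results had been seen. For each list a score per mouse was the mean log2 value of its measured genes, centred on the 10 floxed controls. The genes changed at least 2-fold by loss of FADD or of CASP8, without the targeted and Y-linked genes, were scored in the mice of the other series, as mean rising minus mean falling genes divided by 2. Scores were compared by two-sided exact permutation tests over all 126 distinct splits of 5 against 5, whose smallest p is 0.0079, adjusted over the 13 comparisons of this score. Across genes, Pearson's r and Spearman's rho of the changes after FADD and CASP8 loss were set against 100 random relabellings of the arrays; genes are not independent replicates.

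Alternatives were a fit of only the groups compared, the title series or a sex index as a covariate, quantile normalization, centring of each array on its median, a filter on dim genes, all probes, array weights, eBayes with trend and robust estimation, stricter thresholds, a fit without the triple mutants, and leaving out each mouse in turn. The sex index was the negative mean of 3 Y-linked genes, Eif2s3y, Kdm5d and Uty; Xist and Ddx3y were not analysed here. Added after the data had been seen were the correlations without Paneth cell genes, a circadian clock index as a covariate and a fit without FADD IEC-KO replicate 1 and CASP8 IEC-KO replicate 1. Each count was also compared with 100 random splits of the same arrays. Simulated data (FADD IEC-KO against Fadd fl/fl) had 200 of 19494 genes changed. The workflow called 54% of changes of 0.5 (log2) and 100% of changes of 1, 2 or 3. It called 9 unchanged genes (4.84% of calls), the moved list and 1 of 23 unmoved lists. Unequal spread and correlated list genes, as here, can change these rates.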

Results

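Gene expression was measured in the ileum of 45 mice, 1 array each, in 9 groups of 5. A pair of floxed control groups, Fadd fl/fl and Casp8 fl/fl, was set beside mice that lack FADD or caspase-8 (CASP8) in intestinal epithelial cells (FADD IEC-KO and CASP8 IEC-KO). FADD is the adaptor that recruits caspase-8 to death receptors, and both restrain necroptosis. The other groups combine these deletions with loss of ZBP1, a nucleic acid sensor, of RIPK3, the kinase of necroptosis, or of MLKL, its executioner: FADD IEC-KO Mlkl-/-, FADD IEC-KO Zbp1-/-, FADD IEC-KO RIPK3 IEC-KO, CASP8 IEC-KO Mlkl-/- and FADD IEC-KO CASP8 IEC-KO Mlkl-/- (the triple mutants). Values are log2 intensities. Each array correlated across genes with the others of its group at a median r of 0.981 or more.

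The targeted genes were examined first in every group. Fadd was 7.53 ± 0.06 (SD, n = 5) in Fadd fl/fl, 7.43 ± 0.12 in Casp8 fl/fl, 7.45 ± 0.22 in CASP8 IEC-KO and 7.45 ± 0.19 in CASP8 IEC-KO Mlkl-/-. It was 6.45 ± 0.52 in FADD IEC-KO, 6.11 ± 0.22 in FADD IEC-KO Mlkl-/-, 6.17 ± 0.28 in FADD IEC-KO Zbp1-/-, 6.13 ± 0.17 in FADD IEC-KO RIPK3 IEC-KO and 6.05 ± 0.44 in the triple mutants, whose genotype field does not name Fadd. FADD IEC-KO replicate 1 had 7.31, nearer to the controls than to its group. Casp8 was 11.35 ± 0.09 in Casp8 fl/fl, 11.32 ± 0.19 in Fadd fl/fl, 10.23 ± 0.51 in CASP8 IEC-KO, 9.84 ± 0.21 in CASP8 IEC-KO Mlkl-/- and 9.55 ± 0.09 in the triple mutants, against 11.14 to 11.40 in the other groups without FADD. CASP8 IEC-KO replicate 1 had 10.89. Whole ileum also holds cells that keep the floxed genes.

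Mlkl was 8.66 ± 0.35 in Fadd fl/fl, 8.62 ± 0.21 in Casp8 fl/fl, 9.14 ± 0.41 in FADD IEC-KO, 8.99 ± 0.26 in CASP8 IEC-KO, 9.28 ± 0.48 in FADD IEC-KO Zbp1-/- and 8.76 ± 0.42 in FADD IEC-KO RIPK3 IEC-KO. It was 8.05 ± 0.22 in FADD IEC-KO Mlkl-/- and 7.14 ± 0.19 in the triple mutants, but 8.43 ± 0.22 in CASP8 IEC-KO Mlkl-/-, a level that did not differ from Casp8 fl/fl (log2 fold change -0.19 ± 0.20 SE, adjusted p = 0.769). Mlkl thus does not check the label of that group; the probe's place relative to the deleted part was not known. Ripk3 was 7.50 ± 0.17 in FADD IEC-KO RIPK3 IEC-KO and between 8.03 and 8.94 in the other groups. Zbp1, which interferon induces, was 6.04 ± 0.31 in FADD IEC-KO Zbp1-/-, 7.14 ± 0.73 in Fadd fl/fl, 7.31 ± 0.46 in Casp8 fl/fl, 6.96 ± 0.80 in FADD IEC-KO, 6.87 ± 0.16 in CASP8 IEC-KO and 6.85 ± 0.73 in FADD IEC-KO RIPK3 IEC-KO. It was 7.92 ± 0.18, 8.38 ± 0.14 and 8.04 ± 0.23 in FADD IEC-KO Mlkl-/-, CASP8 IEC-KO Mlkl-/- and the triple mutants.

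Loss of epithelial FADD lowered Paneth cell genes most. The alpha-defensin Defa28, an antimicrobial peptide of Paneth cells, fell by 3.91 ± 0.48 on the log2 scale (SE, 5 mice per group, adjusted p = 2.40e-06), the Paneth cell ribonuclease Ang4 by 3.61 ± 0.54, Clps by 3.36 ± 0.39, Defa26 by 3.36 ± 0.50, Defa34 by 3.22 ± 0.60 and Defa41 by 3.12 ± 0.50. Among genes that separated all mice, the interleukin-1 receptor antagonist Il1rn rose by 2.77 ± 0.40 (adjusted p = 4.27e-05), followed by Myot (1.87 ± 0.36), the fatty acid hydroxylase Fa2h (1.74 ± 0.26), Akr1b8 (1.45 ± 0.32), annexin Anxa1 (1.45 ± 0.33) and Tnf (1.44 ± 0.25). All 14 alpha-defensins on the list fell (camera adjusted p = 2.65e-27, 0.0460 with an estimated correlation), and so did 10 of 11 other Paneth cell markers (2.00e-25, 0.0046 with an estimated correlation), with the mucosal pentraxins Mptx1 and Mptx2 down by 4.25 ± 0.73 and 3.88 ± 0.65. Adjusted over the list alone, the counts were the same, 14 and 10.

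Other cell types moved less in FADD IEC-KO. Of 15 enteroendocrine genes, 3 fell (5 adjusted over the list alone), among them the hormone genes Gcg (-1.02 ± 0.19), Sst (-0.74 ± 0.15) and Pyy (-0.62 ± 0.12, list adjusted p = 0.237 with an estimated correlation). Among 13 tuft cell genes, Dclk1 fell (-0.48 ± 0.13, 3 adjusted over the list alone, list 0.226 with an estimated correlation), and among 15 goblet cell genes Clca1 (-0.45 ± 0.12, 3 adjusted over the list alone, 0.571 with an estimated correlation). The lists of macrophages, fibroblasts, endothelium and smooth muscle were lower. Of macrophage genes, 4 of 15 fell (10 adjusted over the list alone, list 0.260 with an estimated correlation): Lyz2, a myeloid lysozyme close in sequence to Lyz1 of Paneth cells, by 2.17 ± 0.31, C1qb by 0.71 ± 0.21 and Csf1r by 0.61 ± 0.17. Of fibroblast genes, 2 of 13 fell (9 adjusted over the list alone, 0.237 with an estimated correlation), Postn (-0.96 ± 0.20) and Sparc (-0.74 ± 0.17). Of endothelial genes 2 of 10 fell (7 adjusted over the list alone, 0.237 with an estimated correlation), Eng (-0.74 ± 0.21) and Tie1 (-0.39 ± 0.11), and of smooth muscle genes 1 of 13 (3 adjusted over the list alone, 0.424 with an estimated correlation), Cnn1 (-0.75 ± 0.23).

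Higher lists in FADD IEC-KO were proliferation (1 of 19 rose, Rrm2 by 0.60 ± 0.17, 8 adjusted over the list alone, 0.372 with an estimated correlation), fetal-like epithelium (3 of 10, Il1rn, Anxa1 and Anxa3 at 0.75 ± 0.19, 5 rose and 1 fell adjusted over the list alone, 0.260 with an estimated correlation) and neutrophils (1 of 13, S100a8 by 1.45 ± 0.28, 4 adjusted over the list alone, 0.320 with an estimated correlation). The type I interferon list was lower, with 2 of 23 genes down, Rtp4 (-0.84 ± 0.23) and Ifi27l2a (-0.47 ± 0.14), and 3 adjusted over the list alone (0.526 with an estimated correlation). Within the inflammasome list, the gasdermin C genes Gsdmc4, Gsdmc3 and Gsdmc2 fell by 1.99 ± 0.34, 1.97 ± 0.35 and 1.84 ± 0.33 (4 of 19 fell and 1 rose, also adjusted over the list alone, 0.372 with an estimated correlation). Apoa4, an enterocyte apolipoprotein, rose by 1.98 ± 0.35.

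In all, 727 genes changed after FADD loss, 353 up and 374 down, 91 of them at least 2-fold. With each array centred on its median, 534 were up and 349 down. After quantile normalization they were 508 and 415. A filter on dim genes gave 1152. A fit of only these 2 groups called 153. Leaving out FADD IEC-KO replicate 2 or 3 gave 351 or 309 genes, and leaving out Fadd fl/fl replicate 4 or 5 gave 474 or 391. Complete separation held for 747 genes (3.83%, against 0.794% by chance). Of 56 named calls, 30 held in every leave-out and 23 were lost without FADD IEC-KO replicate 2. Camera called 17 of 47 lists, 5 up and 12 down. Both Paneth cell lists held with an estimated correlation.

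Loss of epithelial CASP8 lowered Paneth cell genes, alpha-defensins among them, and raised Car1 and Il1rn most. Defa28 fell by 3.43 ± 0.48 (5 mice per group, adjusted p = 3.33e-05), Defa34 by 3.38 ± 0.60, Defa26 by 3.07 ± 0.50, and, among genes that separated all mice, Defa43 by 2.82 ± 0.53, Defa17 and Defa3 each by 2.74 ± 0.46, Defa39 by 2.70 ± 0.44, and Defa20 and Defa32 each by 2.63 ± 0.50. Defa17 and Defa3 had identical values in all 45 arrays, as did Defa20 and Defa32, so each pair is a single measurement. Of the 14 measured alpha-defensins on the list 13 were distinct. The carbonic anhydrase Car1 rose by 4.09 ± 0.70 (adjusted p = 4.51e-04), Il1rn by 2.62 ± 0.40 (1.00e-04). Among genes that separated all mice, rises followed in the serpin Serpinb5 by 1.55 ± 0.20, the glutathione transferases Gsta2 and Gsta4 by 1.46 ± 0.19 and 1.24 ± 0.22, and S100a6 by 1.33 ± 0.19. Ripk3 rose by 0.91 ± 0.16 (adjusted p = 7.46e-04) and Casp8 fell by 1.12 ± 0.14 (3.20e-06).

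Alpha-defensins fell in 14 of 14 (14 adjusted over the list alone, camera 1.95e-27, 0.0450 with an estimated correlation), other Paneth cell markers in 9 of 11 (11 adjusted over the list alone, 0.0347 with an estimated correlation), led by Mptx1 (-3.60 ± 0.73), Mptx2 (-3.50 ± 0.65) and Ang4 (-2.66 ± 0.54). Of goblet cell genes, 10 of 15 fell, also adjusted over the list alone (5.95e-10, 0.0673 with an estimated correlation), with the mucus proteins Clca1 (-0.67 ± 0.12) and Fcgbp (-0.58 ± 0.10) and with Sytl2 (-0.49 ± 0.12). The enteroendocrine genes Gcg (-0.78 ± 0.19) and Pyy (-0.53 ± 0.12) fell (2 of 15, 4 adjusted over the list alone, 0.306 with an estimated correlation). MHC class II genes fell in 2 of 8, H2-DMb2 (-1.17 ± 0.30) and Ciita (-0.87 ± 0.26), with 8 adjusted over the list alone (1.15e-06, 0.306 with an estimated correlation). Interferon gamma genes fell in 1 of 17, Ido1 (-1.62 ± 0.38, 1 adjusted over the list alone, 0.564 with an estimated correlation). Lyz2 fell by 1.70 ± 0.31 among 15 macrophage genes (2 adjusted over the list alone, 0.602 with an estimated correlation). Fetal-like genes rose in 4 of 10 (5 adjusted over the list alone, 0.306 with an estimated correlation), among them Anxa1 (1.22 ± 0.33) and Ereg (0.72 ± 0.16). Xenobiotic genes rose in 3 of 23 (6 adjusted over the list alone, 0.765 with an estimated correlation), Gsta4, Cyp2c65 (1.24 ± 0.27) and Gstm1 (0.62 ± 0.17). The immediate early genes Egr1 (1.22 ± 0.27) and Junb (0.46 ± 0.09) rose (2 of 9, 4 adjusted over the list alone, 0.306 with an estimated correlation), and so did Pcna (0.38 ± 0.09) among 19 proliferation genes (9 adjusted over the list alone, 0.443 with an estimated correlation).

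After CASP8 loss 813 genes changed, 564 up and 249 down, 58 at least 2-fold, but a fit of only these 2 groups called 10. A filter on dim genes gave 1284 and the clock index as a covariate 1392. Without CASP8 IEC-KO replicate 1 the count was 1354, without replicates 2, 3 and 4 it was 204, 459 and 460, and without Casp8 fl/fl replicates 1, 2 and 3 it was 538, 410 and 421. All mice separated in 832 genes (4.27%, against 0.794% by chance). Of 44 named calls, 28 held in every leave-out, 15 were lost without CASP8 IEC-KO replicate 2, and 3 held in the fit of these groups alone. Camera called 17 lists, 5 up and 12 down, of which both Paneth cell lists held with an estimated correlation.

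The changes after FADD and CASP8 loss, from comparisons that share no array, correlated across 19494 genes at Pearson r = 0.61 and Spearman rho = 0.45, with 65.1% of genes of the same sign. Genes are not independent replicates, so this was set against 100 random relabellings, in which r lay between -0.58 and 0.55. Without the Paneth cell lists r was 0.55, against -0.54 to 0.49 in the relabellings of those genes. Without any further Defa, Mptx or Ang gene as well it was 0.53, and 1 of 100 relabellings gave as large an absolute r (-0.53 to 0.47). Of the called genes, 147 rose in both (10.2 expected), 57 fell in both (4.78 expected) and 1 moved oppositely. The interaction of the 2 deletions called 0 genes (limma, 1271 at an unadjusted p under 0.05). Leaving out 1 mouse gave 0 to 10, with 10 without Fadd fl/fl replicate 1, 6 without FADD IEC-KO replicate 5 and 4 without replicate 4, and 1 without each of Casp8 fl/fl replicate 4, CASP8 IEC-KO replicates 1 and 5 and FADD IEC-KO replicate 1. Camera called 10 lists in this interaction, 0 with an estimated correlation and 0 by fry; in none of them did a gene pass over all genes. With 0 genes called over all genes and 0 adjusted over the list alone in either list, goblet cell genes stood higher in the FADD contrast (mean 0.20, 0.924 with an estimated correlation, Muc2 0.21 ± 0.09, adjusted p = 0.664) and xenobiotic genes lower (mean -0.42, 0.924 with an estimated correlation, Cyp4f14 -0.12 ± 0.12).

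**Figure D1:**
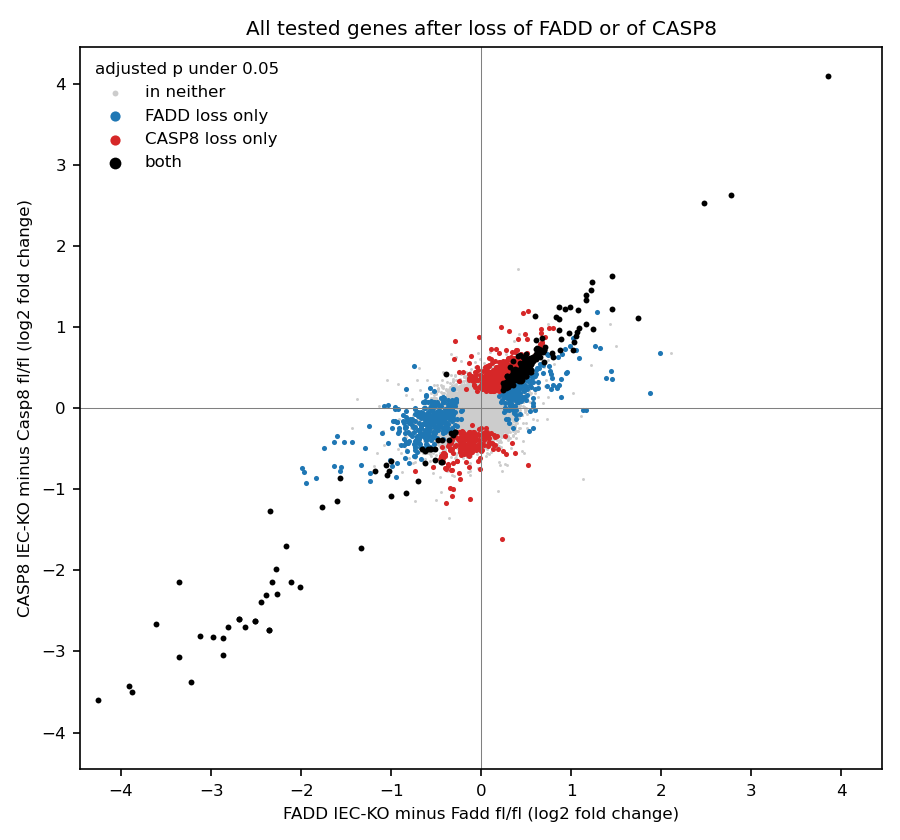
Log2 fold change of each of 19494 genes after loss of CASP8 (vertical axis) against that after loss of FADD (horizontal axis), 5 mice per group; colours mark an adjusted p under 0.05. Pearson r is 0.61, with 147 genes higher and 57 lower in both.

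FADD IEC-KO Mlkl-/- exceeded FADD IEC-KO in interferon-induced genes. Trim30a rose by 2.88 ± 0.35 (5 mice per group, adjusted p = 6.21e-07), Ubd by 2.43 ± 0.54, the ubiquitin-like modifier Isg15 by 2.37 ± 0.28, the antiviral Oas2 by 2.25 ± 0.20 (8.27e-10), Phf11d by 2.16 ± 0.28 and Rtp4 by 2.15 ± 0.23. The adenosine deaminase Ada fell by 2.38 ± 0.26 (7.93e-08), Anxa1 by 2.17 ± 0.33, the nucleoside transporter Slc28a2 by 1.97 ± 0.34, Myot by 1.85 ± 0.36, Cyp2c65 by 1.82 ± 0.27 and Susd2 by 1.76 ± 0.24. Mlkl fell by 1.10 ± 0.20 (5.17e-04). Of the type I interferon list, 22 of 23 rose (23 adjusted over the list alone, camera 3.72e-78, 1.22e-04 with an estimated correlation).

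Interferon gamma genes rose in 4 of 17 (9 adjusted over the list alone, 0.259 with an estimated correlation), with Ido1 at 1.47 ± 0.38, the guanylate-binding protein Gbp9 at 1.26 ± 0.25 and Irgm1 at 1.09 ± 0.28, and MHC class I genes in 5 of 10 (10 adjusted over the list alone, 0.0926 with an estimated correlation), with the immunoproteasome genes Psmb8 (1.22 ± 0.31) and Psmb9 (1.18 ± 0.29) and with Tap2 (0.61 ± 0.13). The MHC class II list was higher with 0 of 8 genes called and 6 adjusted over the list alone (0.310 with an estimated correlation, H2-Ab1 0.89 ± 0.36, adjusted p = 0.299). Alpha-defensins were higher on average (mean 0.79), with 0 of 14 genes called in either adjustment, the one over the list alone included (camera 1.53e-05, 0.434 with an estimated correlation, Defa24 0.62 ± 0.39, adjusted p = 0.607). Pyy (0.86 ± 0.12) and Gcg (0.73 ± 0.19) rose among enteroendocrine genes (2 of 15, 4 rose and 1 fell adjusted over the list alone, 0.406 with an estimated correlation). Among inflammatory genes, 3 of 29 rose and 1 fell, and as many adjusted over the list alone (0.298 with an estimated correlation): Il18 by -1.29 ± 0.28, the NF-kB subunit Nfkb2 by 0.82 ± 0.09 and its inhibitor Nfkbia by 0.50 ± 0.11. The neutrophil genes S100a8 (-1.25 ± 0.28) and Retnlg (-0.70 ± 0.19) fell (2 of 13, 3 adjusted over the list alone, 0.109 with an estimated correlation), as did Egr1 (-1.06 ± 0.27) and Jun (-0.44 ± 0.10) among 9 immediate early genes (3 adjusted over the list alone, 0.0926 with an estimated correlation).

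This comparison called 313 genes, 167 up and 146 down, 80 at least 2-fold. The fit of these 2 groups alone called 145, array weights gave 497, and without FADD IEC-KO replicate 2 the count was 205. Complete separation held for 588 genes (3.02%, against 0.794% by chance). Of 43 named calls 22 held in every leave-out, and 14 were lost without FADD IEC-KO replicate 2. Camera called 22 lists, 14 up and 8 down. The type I interferon list held with an estimated correlation.

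CASP8 IEC-KO Mlkl-/- exceeded CASP8 IEC-KO in interferon-induced and Paneth cell genes. Trim30a rose by 3.28 ± 0.35 (5 mice per group, adjusted p = 2.62e-08), the antiviral Rsad2 by 2.59 ± 0.25, Slfn5 by 2.59 ± 0.24, Oas2 by 2.54 ± 0.20, the deISGylase Usp18 by 2.54 ± 0.34 and Herc6 by 2.51 ± 0.32. Car1 fell by 4.09 ± 0.70 (1.82e-04), Cyp2c55 by 2.37 ± 0.61, Il1rn by 2.22 ± 0.40, Paqr8 by 1.96 ± 0.26, and the clock genes Nr1d1 and Per3 by 1.83 ± 0.34 and 1.64 ± 0.46. Zbp1 rose by 1.51 ± 0.29 (8.65e-04) and Ripk3 fell by 0.60 ± 0.16 (0.0309); Mlkl did not pass (-0.56 ± 0.20, adjusted p = 0.132).

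All 14 alpha-defensins rose (14 adjusted over the list alone, camera 3.38e-30, 0.0299 with an estimated correlation), Defa34 by 3.25 ± 0.60, Defa28 by 2.98 ± 0.48 and Defa26 by 2.83 ± 0.50. Other Paneth cell markers rose in 5 of 11 (9 adjusted over the list alone, 0.0486 with an estimated correlation), with Mptx2 at 3.51 ± 0.65, Mptx1 at 3.32 ± 0.73 and Defa30, which is on both lists, at 2.03 ± 0.37. Goblet cell genes rose in 4 of 15 (8 adjusted over the list alone, 0.0756 with an estimated correlation), Clca1 (0.72 ± 0.12), Atoh1 (0.40 ± 0.11) and Fcgbp (0.39 ± 0.10) among them. All 23 type I interferon genes rose, as many adjusted over the list alone (camera 1.22e-86, 4.85e-05 with an estimated correlation). So did 11 of 17 interferon gamma genes (16 adjusted over the list alone, 0.0560 with an estimated correlation), with Igtp at 2.15 ± 0.53, Ido1 at 1.74 ± 0.38 and Iigp1 at 1.67 ± 0.46, and 7 of 10 MHC class I genes (10 adjusted over the list alone, 0.0560 with an estimated correlation), with the peptide transporter Tap1 at 1.36 ± 0.32, Psmb8 at 1.15 ± 0.31 and H2-T23 at 0.80 ± 0.14.

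MHC class II genes were higher with 1 of 8 called, H2-DMb2 (1.05 ± 0.30, 8 adjusted over the list alone, 0.119 with an estimated correlation), intraepithelial lymphocyte genes with 1 of 15, Itgae (0.78 ± 0.22, 5 adjusted over the list alone, 0.0973 with an estimated correlation), and macrophage genes with 1 of 15, Lyz2 (1.19 ± 0.31, 3 adjusted over the list alone, 0.271 with an estimated correlation). Immediate early genes fell in 3 of 9 (4 adjusted over the list alone, 0.0756 with an estimated correlation): Egr1 (-1.35 ± 0.27), Fos (-1.08 ± 0.23) and Junb (-0.39 ± 0.09). Fetal-like genes fell in 2 of 10, Il1rn and Ereg (-0.63 ± 0.16, 4 adjusted over the list alone, 0.244 with an estimated correlation). Clock genes moved both ways (2 of 14 rose and 4 fell, 4 and 8 adjusted over the list alone, 0.257 with an estimated correlation), with Dbp at -2.51 ± 0.67.

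The comparison called 541 genes, 309 up and 232 down, 132 at least 2-fold. Leave-outs gave 392 to 721. The clock index as a covariate gave 901. Array weights gave 1083. All mice separated in 818 genes (4.20%, against 0.794% by chance). Of 54 named calls 29 held in every leave-out, and 19 were lost without CASP8 IEC-KO replicate 2. Camera called 19 lists, 14 up and 5 down, of which the type I interferon list and both Paneth cell lists held with an estimated correlation. With the comparison in mice without FADD, which shares no array, 104 genes rose in both (2.65 expected), 26 fell in both (1.74 expected) and 1 moved oppositely. The interaction, MLKL loss without FADD minus MLKL loss without CASP8, called 11 genes, 6 up and 5 down. The count was 7 without CASP8 IEC-KO replicate 3, 25 without its replicate 1 and 22 without FADD IEC-KO replicate 4. Gsta2 (1.50 ± 0.26, adjusted p = 0.0085), Cntnap1 (1.24 ± 0.22) and Adss (0.75 ± 0.12) were higher, and Enpp3 (-1.53 ± 0.28), Pdgfc (-0.85 ± 0.16) and the interleukin-22 receptor Il22ra1 (-0.84 ± 0.15) lower. Camera called 7 lists there, 1 up and 6 down, with 0 held by an estimated correlation and 0 called by fry. Alpha-defensins were lower with 0 of 14 called and 11 adjusted over the list alone (mean -1.59, 0.369 with an estimated correlation, Defa24 -1.45 ± 0.55, adjusted p = 0.568), and other Paneth cell markers with 0 of 11 called and 9 adjusted over the list alone (0.234 with an estimated correlation, Lyz1 -1.81 ± 0.46, adjusted p = 0.175).

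**Figure D2:**
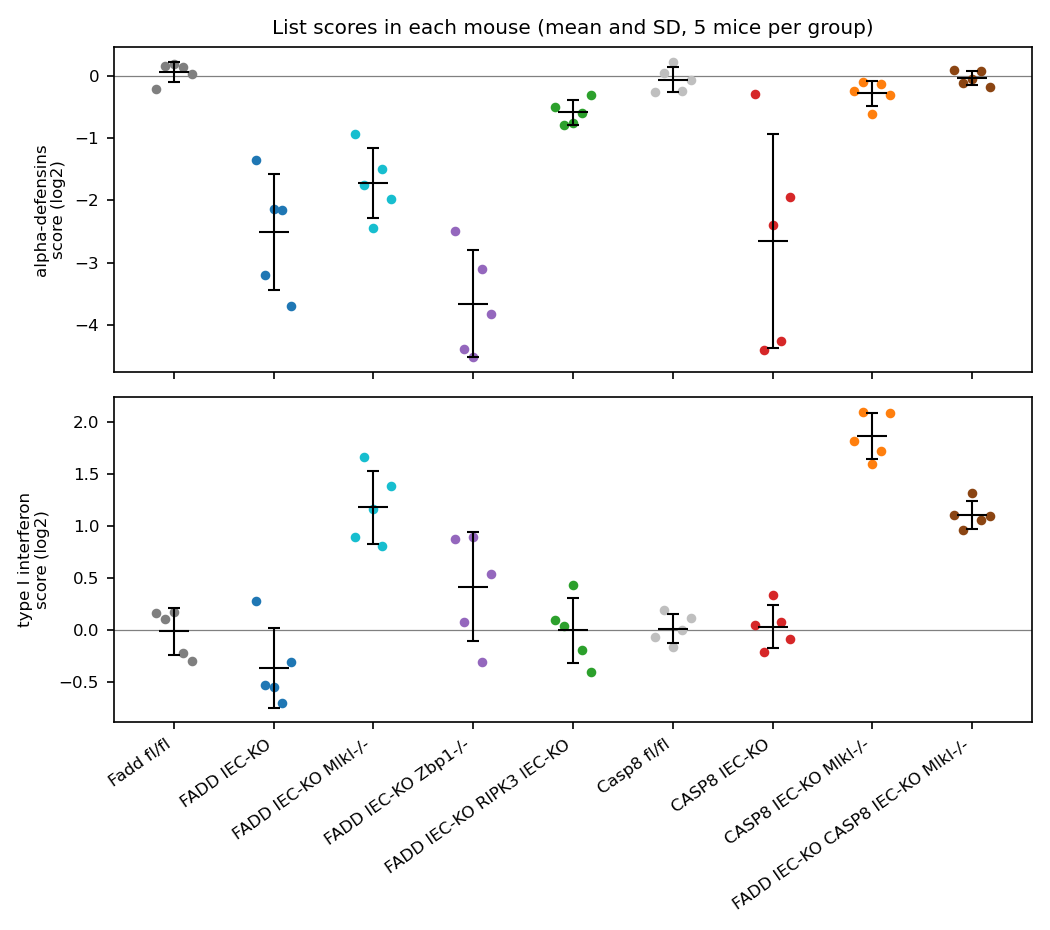
Mean log2 value of the 14 alpha-defensins (upper panel) and the 23 type I interferon genes (lower panel), centred on the 10 floxed controls, in each mouse (points) of the 9 groups; bars are the group mean and SD (n = 5). Alpha-defensins are near 0 in the triple mutants and interferon genes lie at 1.11 to 1.86 in the 3 Mlkl-/- groups.

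ZBP1 loss in mice without epithelial FADD changed many genes slightly. Among called genes that separated all mice, the largest rises were Apol9a (0.83 ± 0.14, 5 mice per group, adjusted p = 0.0016), Dntt (0.69 ± 0.18), Gsta2 (0.67 ± 0.19), Aldh7a1 (0.65 ± 0.12), Morn4 (0.61 ± 0.12) and Sptb (0.60 ± 0.17). The largest falls among such genes were Defa25 (-1.22 ± 0.33, adjusted p = 0.0325), the hormone gene Stc2 (-1.16 ± 0.30), the adhesion molecule Selp (-1.08 ± 0.27), Mtfr2 (-0.97 ± 0.22), the sodium channel subunit Scnn1g (-0.96 ± 0.19) and the eosinophil chemokine Ccl11 (-0.94 ± 0.27). Zbp1 itself did not pass against FADD IEC-KO (-0.93 ± 0.29, adjusted p = 0.0653).

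Of type I interferon genes, 8 of 23 rose (19 adjusted over the list alone, camera 1.79e-20, 0.346 with an estimated correlation), with Isg15 at 1.49 ± 0.28, Rtp4 at 1.43 ± 0.23 and Oas2 at 1.08 ± 0.20. Alpha-defensins were lower than in FADD IEC-KO (mean -1.15), with Defa25 alone of 14 called and 8 adjusted over the list alone (5.80e-07, 0.608 with an estimated correlation); 0 of 11 other Paneth cell markers passed, over the list alone included (0.839 with an estimated correlation, Lyz1 -0.44 ± 0.32). Proliferation genes fell in 4 of 19 (12 adjusted over the list alone, 0.608 with an estimated correlation), with the mitotic genes Kif11 (-0.70 ± 0.17), Tpx2 (-0.57 ± 0.12) and Mki67 (-0.52 ± 0.11), and the crypt gene Slc12a2 fell by 0.61 ± 0.13 (1 of 10, as many adjusted over the list alone, 0.662 with an estimated correlation). Smooth muscle genes were higher with 0 of 13 called and 10 adjusted over the list alone (9.07e-08, 0.608 with an estimated correlation, Acta2 0.33 ± 0.15, adjusted p = 0.226), and MHC class I genes with 0 of 10 called and 4 adjusted over the list alone (0.662 with an estimated correlation, B2m 0.10 ± 0.10, adjusted p = 0.655).

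In this comparison 648 genes were called, 167 up and 481 down, 12 at least 2-fold. After quantile normalization 247 were up and 378 down. The fit of these 2 groups alone called 0 (limma). Array weights gave 337, a filter on dim genes 1001 and the title series as a covariate 998. The count was 336, 239, 1041 and 309 without FADD IEC-KO replicates 2, 3, 4 and 5, and 298, 1010, 418 and 246 without FADD IEC-KO Zbp1-/- replicates 1, 3, 4 and 5. Complete separation held for 539 genes (2.77%, against 0.794% by chance). Of 33 named calls 14 held in every leave-out and 0 in the fit of these groups alone; 18 were lost without FADD IEC-KO replicate 3. Camera called 14 lists, 8 up and 6 down, 0 of them with an estimated correlation and 1 by fry.

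Epithelial RIPK3 loss in mice without FADD raised alpha-defensins. Defa26 rose by 2.85 ± 0.50 (5 mice per group, adjusted p = 0.0021), Defa28 by 2.68 ± 0.48, Defa34 by 2.44 ± 0.60, Defa43 by 2.36 ± 0.53, Defa41 by 2.30 ± 0.50 and Defa39 by 2.17 ± 0.44. Among genes that separated all mice, those that fell most were Il1rn (-2.20 ± 0.40, adjusted p = 0.0026), Myot (-1.97 ± 0.36), Anxa1 (-1.91 ± 0.33), the retinol dehydrogenase Dhrs9 (-1.55 ± 0.37), Akr1b8 (-1.44 ± 0.32) and Tnf (-1.25 ± 0.25). Ripk3 fell by 1.25 ± 0.16 (3.53e-05). On the list, 11 of 14 alpha-defensins rose (14 adjusted over the list alone, camera 3.66e-20, 0.196 with an estimated correlation), and 2 of 11 other Paneth cell markers did, Defa30 (1.55 ± 0.37) and the lysozyme Lyz1 (1.22 ± 0.32, 8 rose and 1 fell adjusted over the list alone, 0.283 with an estimated correlation).

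Enterocyte genes rose in 2 of 23, Enpep (0.46 ± 0.12) and villin Vil1 (0.27 ± 0.07, 7 rose and 1 fell adjusted over the list alone, 0.347 with an estimated correlation), and enteroendocrine genes in 2 of 15, Nts (1.15 ± 0.28) and Pyy (0.80 ± 0.12, 4 adjusted over the list alone, 0.409 with an estimated correlation). Neutrophil genes fell in 3 of 13 (4 adjusted over the list alone, 0.196 with an estimated correlation): S100a8 (-1.01 ± 0.28), S100a9 (-0.83 ± 0.19) and Il1r2 (-0.48 ± 0.13). Proliferation genes fell in 1 of 19, Tpx2 (-0.47 ± 0.12, 5 adjusted over the list alone, 0.309 with an estimated correlation), inflammatory genes in 1 of 29, Tnf (7 adjusted over the list alone, 0.283 with an estimated correlation), and immediate early genes in 1 of 9, Egr1 (-1.21 ± 0.27, 1 adjusted over the list alone, 0.283 with an estimated correlation). Type I interferon genes were higher with 0 of 23 called and 6 adjusted over the list alone (1.16e-05, 0.452 with an estimated correlation, Oasl2 0.44 ± 0.25, adjusted p = 0.439). The gasdermins Gsdmc4, Gsdmc3 and Gsdmc2 rose by 1.62, 1.59 and 1.50, and the antimicrobial lectin Reg3a by 1.22 ± 0.30.

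RIPK3 loss changed 303 genes, 162 up and 141 down (179 and 195 after quantile normalization), 64 at least 2-fold. A fit of these 2 groups alone called 19, the sex index as a covariate left 126 and the clock index 46. Array weights gave 488. All 5 FADD IEC-KO RIPK3 IEC-KO mice had high Y-linked expression, against 2 of 5 FADD IEC-KO, 3 of 5 Fadd fl/fl and 3 of 5 FADD IEC-KO Mlkl-/- mice. The comparisons of RIPK3 loss were thus partly confounded with sex. Without FADD IEC-KO replicates 2, 3, 4 and 5 the count was 132, 53, 667 and 74, and without FADD IEC-KO RIPK3 IEC-KO replicates 1, 2, 4 and 5 it was 185, 158, 124 and 142. Separation was complete for 508 genes (2.61%, against 0.794% by chance). Of 34 named calls 8 held in every leave-out: Defa26, Defa28, Il1rn, Myot, Anxa1, Ripk3, Pyy and Ces1f. Camera called 20 lists, 11 up and 9 down, 0 with an estimated correlation and 5 by fry.

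The triple mutants exceeded FADD IEC-KO Mlkl-/- mice in Paneth cell and enterocyte genes. Mptx1 rose by 3.20 ± 0.73 (5 mice per group, adjusted p = 0.0047), Ang4 by 3.09 ± 0.54 (3.29e-04), Mptx2 by 2.84 ± 0.65, Defa28 by 2.73 ± 0.48, the glucose transporter Slc2a2 by 2.72 ± 0.57 and Defa26 by 2.44 ± 0.50. Besides Casp8 (-1.78 ± 0.14, adjusted p = 5.28e-12), Gsta2 (-1.58 ± 0.19), Abca13 (-1.26 ± 0.22), Hsd17b6 (-1.20 ± 0.31), Phf11d (-1.17 ± 0.28) and the growth factor Nrg1 (-1.10 ± 0.21) fell most among the named genes that separated all mice. Mlkl, lost in both by label, fell by 0.91 ± 0.20 (0.0027).

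Alpha-defensins rose in 10 of 14 (14 adjusted over the list alone, camera 4.00e-11, 0.351 with an estimated correlation), with Defa34 at 2.37 ± 0.60, and other Paneth cell markers in 10 of 11, and as many adjusted over the list alone (0.206 with an estimated correlation). Enterocyte genes rose in 15 of 23 (18 adjusted over the list alone, 2.35e-14, 0.307 with an estimated correlation), among them the fructose transporter Slc2a5 (1.97 ± 0.44) and the trehalase Treh (1.41 ± 0.28). Smooth muscle genes rose in 12 of 13 (13 adjusted over the list alone, 0.307 with an estimated correlation), with Actg2 at 1.04 ± 0.24, Cnn1 at 0.97 ± 0.23 and desmin Des at 0.97 ± 0.25, and fibroblast genes in 4 of 13 (7 adjusted over the list alone, 0.404 with an estimated correlation), with Postn (0.93 ± 0.20), fibronectin Fn1 (0.80 ± 0.21) and Thy1 (0.39 ± 0.11). Xenobiotic genes rose in 5 of 23 (10 adjusted over the list alone, 0.597 with an estimated correlation), with Cyp3a25 (1.91 ± 0.45), Cyp2d26 (1.45 ± 0.45) and Ephx2 (0.77 ± 0.25), and fatty acid oxidation genes in 5 of 16, and as many adjusted over the list alone (0.590 with an estimated correlation), with Vnn1 (1.43 ± 0.22), Angptl4 (0.83 ± 0.26) and Pdk4 (0.61 ± 0.18). Proliferation genes fell in 3 of 19 (4 adjusted over the list alone, 0.597 with an estimated correlation): Ccna2 (-0.47 ± 0.14), Birc5 (-0.43 ± 0.11) and Mki67 (-0.38 ± 0.11). The type I interferon list was not called, with Mx2 (-0.80) down and Irf7 (0.58) up.

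This comparison called 1533 genes, 1074 up and 459 down, 94 at least 2-fold. The split moved with the scaling: 866 up and 901 down after quantile normalization, 881 and 635 with arrays centred. The count was 935 without triple mutant replicate 1, 667 with the title series as a covariate and 2839 with array weights. All 5 triple mutants and 0 of 5 FADD IEC-KO Mlkl-/- mice had title numbers of 200 and over, so series and genotype cannot be told apart. Complete separation held for 2127 genes (10.9%, against 0.794% by chance). Of 60 named calls 37 held in every leave-out, and 15 were lost without triple mutant replicate 1. Camera called 13 lists, 11 up and 2 down, 0 of them with an estimated correlation and 11 by fry.

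The triple mutants, which add loss of FADD to CASP8 IEC-KO Mlkl-/-, exceeded those mice most in Dbp and Slc2a5. The clock output factor Dbp rose by 3.02 ± 0.67 (5 mice per group, adjusted p = 0.0071), Slc2a5 by 2.43 ± 0.44, Slc2a2 by 2.16 ± 0.57, and the clock repressors Nr1d1, Nr1d2 and Ciart by 2.14 ± 0.34, 1.65 ± 0.34 and 1.55 ± 0.42. Slfn4 fell by 1.79 ± 0.34, Rsad2 by 1.51 ± 0.25, Phf11d by 1.45 ± 0.28, Fadd by 1.40 ± 0.17 (8.25e-06), the clock activator Arntl by 1.38 ± 0.37 and Mlkl by 1.29 ± 0.20 (1.54e-04). With a clock index as a covariate, Arntl (0.12) and Ciart (-0.07) changed sign. The index is the mean of Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per3 and Ciart minus that of Arntl and Npas2. It was -2.62 ± 0.29 (SD) in CASP8 IEC-KO Mlkl-/-, 0.07 ± 0.65 in the triple mutants and -1.31 to 0.45 in the other groups. CASP8 IEC-KO Mlkl-/- thus stood apart, and the clock changes cannot be credited to FADD loss. Against the mean of both floxed groups the clock list of the triple mutants was not called (camera adjusted p = 0.309). The type I interferon genes fell in 10 of 23 (19 adjusted over the list alone, 3.45e-21, 0.153 with an estimated correlation), with Mx2 at -1.71 ± 0.24 and Oas2 at -1.04 ± 0.20. Enterocyte genes rose in 4 of 23 (6 adjusted over the list alone, 0.993 with an estimated correlation), Slc5a1 by 0.45 ± 0.12 among them, and cholesterol genes in 3 of 16 (6 adjusted over the list alone, 0.988 with an estimated correlation): Mvd (0.65 ± 0.15), Insig1 (0.61 ± 0.16) and Srebf2 (0.30 ± 0.07). Clock genes moved both ways, 6 of 14 up and 2 down (10 and 4 adjusted over the list alone, 0.153 with an estimated correlation).

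In total 605 genes were called, 397 up and 208 down, 26 at least 2-fold. The split was 323 up and 335 down after quantile normalization and 327 and 262 with arrays centred. Leaving out CASP8 IEC-KO Mlkl-/- replicates 2, 3 and 4 gave 393, 317 and 396 genes, and leaving out triple mutant replicates 1 and 5 gave 399 and 394. The title series as a covariate left 164 and the clock index 322. With array weights the count was 1479. All 5 triple mutants but only 1 of 5 CASP8 IEC-KO Mlkl-/- mice had title numbers of 200 and over. Separation was complete for 1351 genes (6.93%, against 0.794% by chance). Of 31 named calls 18 held in every leave-out, and 11 were lost without CASP8 IEC-KO Mlkl-/- replicate 3. Camera called 4 lists, 3 up and 1 down, 0 with an estimated correlation and 2 by fry.

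The genes changed at least 2-fold by CASP8 loss (57, targeted genes left out) gave a score per mouse in the mice of the FADD series, and those changed by FADD loss (90) a score in the CASP8 series. The CASP8-loss score was 1.83 ± 0.46 (SD, n = 5) in FADD IEC-KO, 1.20 ± 0.30 in FADD IEC-KO Mlkl-/-, 2.16 ± 0.49 in FADD IEC-KO Zbp1-/-, 0.61 ± 0.04 in FADD IEC-KO RIPK3 IEC-KO and 0.20 ± 0.07 in the triple mutants, against 0 ± 0.13 in Fadd fl/fl. Against FADD IEC-KO it differed by -1.22 with RIPK3 loss (5 of 5 mice lower, exact permutation p = 0.0079, adjusted 0.0129) and by -0.63 with MLKL loss (exact p = 0.0317, adjusted 0.0375), while the difference with ZBP1 loss was 0.33 (exact p = 0.294, adjusted 0.318). The call for MLKL loss ended in 13 of 20 leave-outs, over which the difference ranged from -0.76 to -0.47, and with genes chosen with no fold minimum (-0.11). The triple mutants lay below FADD IEC-KO Mlkl-/- (difference -1.0, exact p = 0.0079, adjusted 0.0129) and 0.20 above Fadd fl/fl (exact p = 0.0238, adjusted 0.0344), a call that ended in 5 of 20 leave-outs (0.11 to 0.32). That call also ended with no fold minimum (0.02) and with the title series taken out of the values (0.15), and the difference was 0.42 as a median over genes.

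In the CASP8 series the FADD-loss score was 1.34 ± 0.72 in CASP8 IEC-KO, 0.28 ± 0.15 in CASP8 IEC-KO Mlkl-/- and 0.21 ± 0.15 in the triple mutants, against 0 ± 0.10 in Casp8 fl/fl. CASP8 IEC-KO Mlkl-/- lay below CASP8 IEC-KO (difference -1.06, exact p = 0.0317, adjusted 0.0375, -0.83 without CASP8 IEC-KO replicate 2, where the call ended). It lay above Casp8 fl/fl (5 of 5 mice higher, exact p = 0.0079, adjusted 0.0129), and the triple mutants did not differ from it (-0.07, exact p = 0.444).

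**Figure D3:**
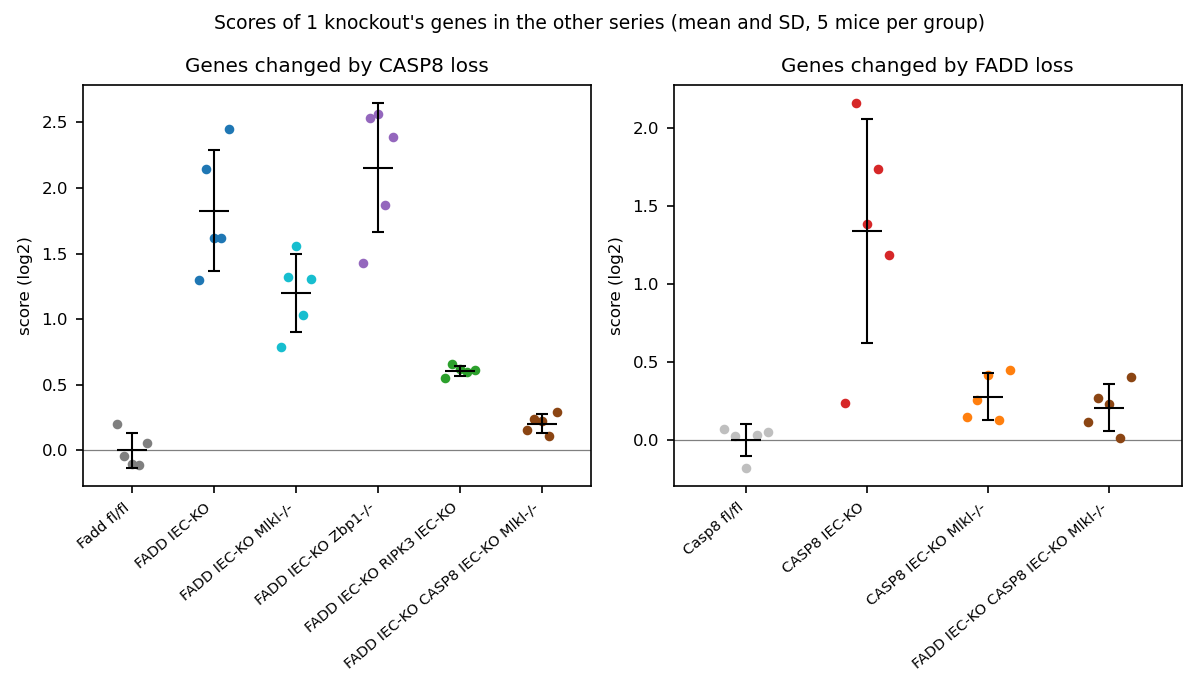
Score (log2) of the genes changed at least 2-fold by CASP8 loss in the FADD series and the triple mutants (left) and of those changed by FADD loss in the CASP8 series and the triple mutants (right); points are mice, bars the group mean and SD (n = 5). The score is 1.83 in FADD IEC-KO, 0.61 with RIPK3 loss and 0.20 in the triple mutants.

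Against Fadd fl/fl, FADD IEC-KO Mlkl-/- mice had lower Paneth cell genes and higher interferon genes. The oxidase Nox1 rose by 3.27 ± 0.57 (5 mice per group, adjusted p = 1.83e-04), Ubd by 2.62 ± 0.54 and Slfn4 by 2.24 ± 0.34, while Ang4 fell by 4.08 ± 0.54, Clps by 3.52 ± 0.39 and Mptx1 by 3.23 ± 0.73. Alpha-defensins fell in 13 of 14 (14 adjusted over the list alone, 0.273 with an estimated correlation), Defa28 by 2.80 ± 0.48, and other Paneth cell markers in 10 of 11 (11 adjusted over the list alone, 0.0268 with an estimated correlation). Type I interferon genes rose in 20 of 23 (22 adjusted over the list alone, 6.87e-29, 0.0418 with an estimated correlation), with Isg15 at 2.08 ± 0.28, Trim30a at 1.97 ± 0.35 and Oas2 at 1.96 ± 0.20. MHC class I genes rose in 6 of 10 (9 adjusted over the list alone, 0.447 with an estimated correlation), with Psmb8 at 1.18 ± 0.31, Psmb9 at 1.01 ± 0.29 and Tap1 at 1.0 ± 0.32, and inflammatory genes in 5 of 29 (5 rose and 1 fell adjusted over the list alone, 0.273 with an estimated correlation), with Tnf at 1.93 ± 0.25, Nfkb2 at 0.88 ± 0.09 and Nfkbia at 0.59 ± 0.11. Fibroblast genes fell in 10 of 13 (13 adjusted over the list alone, 0.0714 with an estimated correlation), with Postn at -1.30 ± 0.20, Col5a1 at -1.01 ± 0.19 and Lum at -0.90 ± 0.28, and smooth muscle genes in 7 of 13 (13 adjusted over the list alone, 0.370 with an estimated correlation), with Cnn1 at -1.15 ± 0.23.

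That comparison called 2040 genes, 803 up and 1237 down (1127 and 1161 after quantile normalization, 1016 and 1066 with arrays centred), 174 at least 2-fold, and 1220 without Fadd fl/fl replicate 5. In it 1922 genes separated (9.86%, against 0.794% by chance) and 52 of 79 named calls held in every leave-out. Camera called 16 lists, 7 up and 9 down. The type I interferon and other Paneth cell lists held with an estimated correlation.

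Against Casp8 fl/fl, CASP8 IEC-KO Mlkl-/- mice had higher interferon genes, with Trim30a at 3.15 ± 0.35 (5 mice per group, adjusted p = 3.19e-08), Oas2 at 2.78 ± 0.20 (6.38e-13) and Slfn4 at 2.75 ± 0.34. All 23 type I interferon genes rose, over the list alone included (1.19e-94, 2.12e-05 with an estimated correlation), Rsad2 by 2.63 ± 0.25 among them, as did 3 of 17 interferon gamma genes, and as many adjusted over the list alone (0.739 with an estimated correlation): Gbp3 (1.16 ± 0.21), Irgm1 (1.12 ± 0.28) and Gbp9 (1.02 ± 0.25). Nr1d1 fell by 1.83 ± 0.34, Casp8 by 1.51 ± 0.14 (3.75e-10) and the creatine transporter Slc6a8 by 1.02 ± 0.18; with Nr1d1 (down) and Cry1 (0.59 ± 0.16) the clock list had 1 of 14 up and 1 down (3 and 8 adjusted over the list alone, 0.301 with an estimated correlation). The alpha-defensin list was not called (mean -0.22), and other Paneth cell markers were lower with 0 of 11 called, over the list alone included (0.0193, 0.923 with an estimated correlation, Lyz1 -0.47 ± 0.32, adjusted p = 0.606). Here 212 genes changed, 151 up and 61 down, 49 at least 2-fold, and 685 separated (3.51%, against 0.794% by chance). The count was 123 without Casp8 fl/fl replicate 3, 135, 125 and 140 without CASP8 IEC-KO Mlkl-/- replicates 2, 3 and 5, 103 with the clock index as a covariate, 339 with a filter on dim genes and 524 with array weights. Camera called 8 lists, 5 up and 3 down. Between this comparison and that of FADD IEC-KO Mlkl-/- with Fadd fl/fl, 93 genes rose in both (6.22 expected), 16 fell in both (3.87 expected) and 4 moved oppositely.

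FADD IEC-KO Zbp1-/- mice differed from Fadd fl/fl most in Paneth cell genes. Mptx2 fell by 5.49 ± 0.65 (5 mice per group, adjusted p = 1.74e-07), Mptx1 by 5.30 ± 0.73 and Defa34 by 4.84 ± 0.60, while Car1 rose by 3.74 ± 0.70, Apoa4 by 2.20 ± 0.35 and Il1rn by 2.17 ± 0.40. Zbp1 fell by 1.11 ± 0.29 (0.0091). All 14 alpha-defensins and all 11 other Paneth cell markers fell, over the list alone included (0.0198 and 0.0077 with an estimated correlation), with Defa28 down by 4.59 ± 0.48, Defa26 by 4.18 ± 0.50 and Ang4 by 4.13 ± 0.54. Goblet cell genes fell in 5 of 15, and as many adjusted over the list alone (0.465 with an estimated correlation), with the secretory factor Creb3l4 at -1.04 ± 0.14, Spink4 at -0.67 ± 0.11 and Sytl2 at -0.35 ± 0.12. Macrophage genes fell in 8 of 15 (11 adjusted over the list alone, 0.351 with an estimated correlation), with Lyz2 at -2.32 ± 0.31, Itgam at -1.26 ± 0.25 and C1qb at -0.88 ± 0.21, and fibroblast genes in 8 of 13 (9 adjusted over the list alone, 0.351 with an estimated correlation), with Postn at -1.09 ± 0.20, Dcn at -0.87 ± 0.22 and Col3a1 at -0.77 ± 0.16. The type I interferon genes rose in 6 of 23 (10 adjusted over the list alone, 0.560 with an estimated correlation), with Isg15 at 1.20 ± 0.28, Irf7 at 0.81 ± 0.17 and Oas2 at 0.80 ± 0.20. The count was 2313 genes, 932 up and 1381 down (1383 and 1194 after quantile normalization, 1299 and 1077 with arrays centred), 144 at least 2-fold. The fit of these groups alone called 820, and without Fadd fl/fl replicate 5 it was 1507. Complete separation held for 1251 genes (6.42%, against 0.794% by chance). Camera called 12 lists, 4 up and 8 down. Both Paneth cell lists held with an estimated correlation.

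Against Fadd fl/fl, FADD IEC-KO RIPK3 IEC-KO mice had higher Mt1, a metallothionein (1.27 ± 0.09, 5 mice per group, adjusted p = 1.06e-12), Gsta2 (1.25 ± 0.19) and Fa2h (1.22 ± 0.26), and lower Ang4 (-2.27 ± 0.54), Clps (-2.12 ± 0.39) and the lectin Itln1 (-1.41 ± 0.32). Of 14 alpha-defensins 0 passed, over the list alone included (camera 0.0011, 0.660 with an estimated correlation, Defa24 -0.49 ± 0.39, adjusted p = 0.619), but other Paneth cell markers fell in 6 of 11 (10 adjusted over the list alone, 8.23e-16, 0.0231 with an estimated correlation). Fibroblast genes fell in 6 of 13 (12 adjusted over the list alone, 0.0217 with an estimated correlation), with Col5a1 at -1.02 ± 0.19, Sparc at -0.89 ± 0.17 and Dcn at -0.82 ± 0.22, and Lyz2 fell by 1.20 ± 0.31 (1 of 15 macrophage genes, 7 adjusted over the list alone, 0.217 with an estimated correlation). Mitochondrial respiration genes rose in 2 of 15, Sdhb (0.28 ± 0.07) and Cox5a (0.28 ± 0.06, 12 adjusted over the list alone, 0.0204 with an estimated correlation). In all 239 genes changed, 110 up and 129 down (150 and 108 with arrays centred), 19 at least 2-fold. The fit of these groups alone called 64. A filter on dim genes gave 432. Without Fadd fl/fl replicates 1, 3, 4 and 5 the count was 454, 109, 81 and 125, and without FADD IEC-KO RIPK3 IEC-KO replicates 2 and 5 it was 143 and 133. All mice separated in 638 genes (3.27%, against 0.794% by chance). Camera called 13 lists, 4 up and 9 down.

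The triple mutants were compared with the mean of both floxed groups. Nox1 was 2.0 ± 0.49 higher (adjusted p = 0.0160), Trim30a 1.98 ± 0.30 and Oas2 1.77 ± 0.18, and Casp8 (-1.78 ± 0.12), Mlkl (-1.50 ± 0.17) and Fadd (-1.43 ± 0.15) fell most. Type I interferon genes rose in 20 of 23 (22 adjusted over the list alone, 1.95e-39, 0.0166 with an estimated correlation), with Isg15 at 1.68 ± 0.24. Inflammatory genes rose in 3 of 29 (7 adjusted over the list alone, 0.365 with an estimated correlation): Tnf (1.37 ± 0.22), Nfkb2 (0.66 ± 0.08) and Tnfaip3 (0.54 ± 0.12). Enterocyte genes rose in 3 of 23 (7 adjusted over the list alone, 0.691 with an estimated correlation): Apoa4 (1.14 ± 0.31), Mttp (0.44 ± 0.10) and Vil1 (0.21 ± 0.06). Neither Paneth cell list was called. The inflammasome sensors Nlrp9b (-0.98 ± 0.18), Naip5 (-0.44 ± 0.10) and Naip6 (-0.39 ± 0.10) fell (3 of 19, 1 rose and 8 fell adjusted over the list alone, 0.691 with an estimated correlation). This gave 720 genes, 419 up and 301 down (306 and 446 after quantile normalization), 38 at least 2-fold, 451 in the fit of these groups alone, 475 with the title series as a covariate and 1192 with array weights. Without triple mutant replicates 1, 2, 3 and 5 the count was 387, 411, 435 and 368. Camera called 12 lists, 8 up and 4 down.

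Compared directly, FADD IEC-KO Zbp1-/- mice had more Car1 (3.08 ± 0.70, 5 mice per group, adjusted p = 0.0070), Ada (1.89 ± 0.26) and Anxa1 (1.81 ± 0.33), and less Mptx2 (-2.61 ± 0.65), Defa34 (-2.47 ± 0.60) and Defa22 (-2.37 ± 0.49), than FADD IEC-KO Mlkl-/- mice. All 14 alpha-defensins were lower, over the list alone included (1.46e-17, 0.254 with an estimated correlation), Defa21 by -2.27 ± 0.52 among them. Of type I interferon genes 10 of 23 were lower (19 adjusted over the list alone, 0.254 with an estimated correlation), with Trim30a at -1.78 ± 0.35, Ifit2 at -1.60 ± 0.25 and Oas2 at -1.16 ± 0.20, and 12 of 13 smooth muscle genes were higher (13 adjusted over the list alone, 0.254 with an estimated correlation), with Actg2 at 0.90 ± 0.24, Pgm5 at 0.85 ± 0.22 and Des at 0.85 ± 0.25. Here 804 genes were called, 344 up and 460 down, 81 at least 2-fold, and 323 in the fit of these groups alone; 901 separated (4.62%, against 0.794% by chance). Without FADD IEC-KO Mlkl-/- replicate 2 the count was 524, and without FADD IEC-KO Zbp1-/- replicates 4 and 5 it was 521 and 467. Camera called 19 lists, 7 up and 12 down, 0 with an estimated correlation and 7 by fry.

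FADD IEC-KO RIPK3 IEC-KO mice had higher Hao2 (2.33 ± 0.33, 5 mice per group, adjusted p = 1.35e-05), Ada (2.22 ± 0.26) and the lactate transporter Slc5a12 (2.22 ± 0.51), and lower Plet1 (-3.36 ± 1.03), Nox1 (-3.24 ± 0.57) and Ubd (-3.09 ± 0.54), than FADD IEC-KO Mlkl-/- mice. Type I interferon genes were lower in 21 of 23 (22 adjusted over the list alone, 0.0189 with an estimated correlation), with Trim30a at -2.32 ± 0.35, Oas2 at -1.88 ± 0.20 and Isg15 at -1.86 ± 0.28, and inflammatory genes in 6 of 29 (7 lower and 1 higher adjusted over the list alone, 0.0258 with an estimated correlation), with Tnf at -1.75 ± 0.25, Nfkb2 at -0.96 ± 0.09 and Nfkbia at -0.89 ± 0.11. Enterocyte genes were higher in 10 of 23 (15 adjusted over the list alone, 0.205 with an estimated correlation), with Slc2a5 at 1.42 ± 0.44, Treh at 1.30 ± 0.28 and the alkaline phosphatase Alpi at 0.99 ± 0.17, and alpha-defensins in 2 of 14, Defa26 (1.88 ± 0.50) and Defa28 (1.57 ± 0.48, 11 adjusted over the list alone, 0.394 with an estimated correlation). In all 966 genes were called, 568 up and 398 down (530 and 533 after quantile normalization), 133 at least 2-fold; 1377 separated (7.06%, against 0.794% by chance). Without FADD IEC-KO RIPK3 IEC-KO replicates 4 and 5 the count was 495 and 442, and without FADD IEC-KO Mlkl-/- replicate 2 it was 567. The clock index as a covariate left 580. With array weights 1456 were called. Camera called 18 lists, 8 up and 10 down.

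Between the control groups 1 gene differed, Pisd-ps3 (-1.02 ± 0.19 in Fadd fl/fl against Casp8 fl/fl, adjusted p = 0.0451), named after its values were seen; 1634 had an unadjusted p under 0.05 and 219 separated (1.12%, against 0.794% by chance). Quantile normalization gave 5 higher and 6 lower, and the fit of these groups alone called 2. The count was 0 without any of Casp8 fl/fl replicates 1 and 3 and Fadd fl/fl replicates 2, 3, 4 and 5, but 63 without Fadd fl/fl replicate 1, 5 without Casp8 fl/fl replicate 4 and 3 without its replicate 5.

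**Figure D4:**
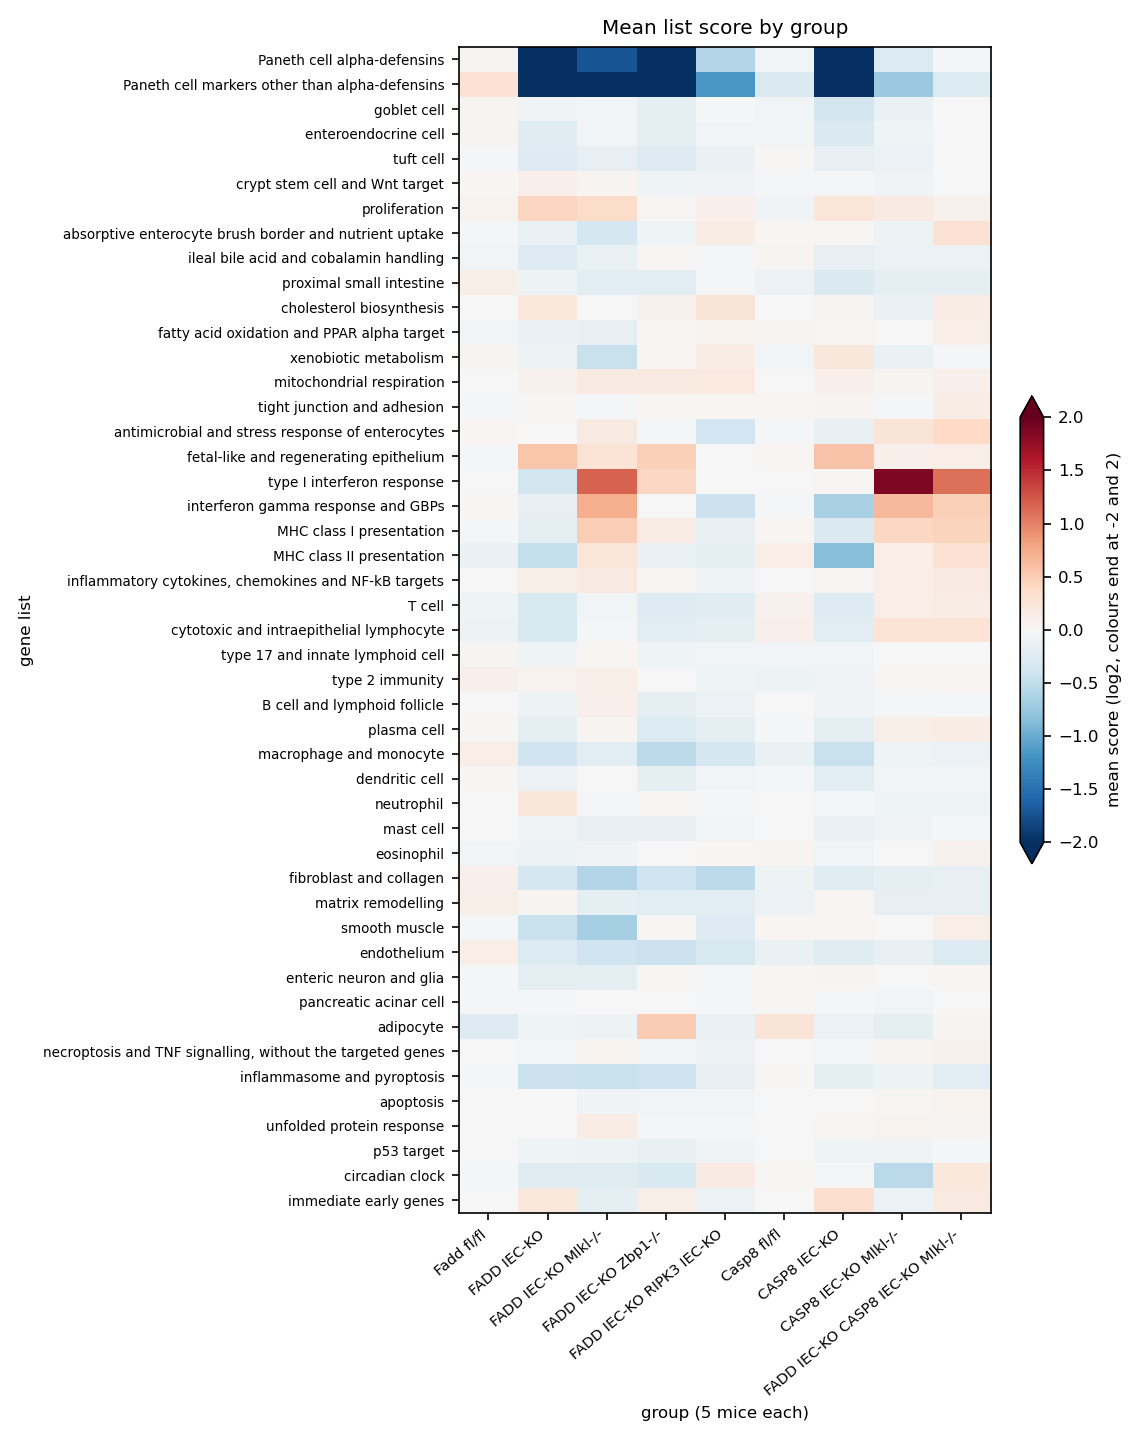
Mean score (log2, centred on the 10 floxed controls) of 47 gene lists (vertical axis) in the 9 groups of 5 mice (horizontal axis); colours end at -2 and 2. Alpha-defensins are at -2.51 in FADD IEC-KO, -3.66 with ZBP1 loss, -1.72 with MLKL loss, -0.59 with RIPK3 loss and -0.03 in the triple mutants.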

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

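The tests of the interferon, clock and replicate 1 patterns below were chosen only after those results had been seen. The outlier, interaction and unnamed probe results come from tests fixed before.

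Single mice far from the others of their group were found in 5 of 73 groups of values, where chance alone would give 3.65. They were Fadd at 7.80 in CASP8 IEC-KO Mlkl-/- replicate 1, Fadd at 6.27 in FADD IEC-KO RIPK3 IEC-KO replicate 1, Mlkl at 8.98 in Casp8 fl/fl replicate 5, Ripk3 at 8.68 in triple mutant replicate 5, and the score of FADD-loss genes at -0.18 in Casp8 fl/fl replicate 3.

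Effects that differed between groups by a test of the difference were 10 gene lists for FADD loss against CASP8 loss, and 11 genes and 7 gene lists for MLKL loss without FADD against MLKL loss without CASP8. All 17 list calls were lost with an estimated correlation.

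Signals also appeared in 2615 probes without a gene name, which were left out of the comparisons except in the setting with all probes. Between the control groups 0 of them changed. Against their floxed controls, 23 changed in FADD IEC-KO, 70 in CASP8 IEC-KO, 141 in FADD IEC-KO Mlkl-/-, 15 in CASP8 IEC-KO Mlkl-/-, 248 in FADD IEC-KO Zbp1-/-, 17 in FADD IEC-KO RIPK3 IEC-KO and 84 in the triple mutants.

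Type I interferon genes were higher in all 3 Mlkl-/- groups than in floxed controls. The title series might explain this, but among mice with numbers under 100 the score differed by 1.82 between CASP8 IEC-KO Mlkl-/- and Casp8 fl/fl (4 against 4, exact permutation p = 0.0286). Against the floxed controls of both lines in the same series it was 1.14 in FADD IEC-KO Mlkl-/- (5 against 6, exact p = 0.0022) and 1.16 in the triple mutants (5 against 4, exact p = 0.0079). In each test the Mlkl-/- title numbers lay below those of all controls, such as 36 to 40 against 63 to 84. Order within a series thus cannot be told apart from genotype. Sex was argued against by the smaller difference within high or low Y-linked expression, 1.34 (exact p = 0.0022). So was FADD or CASP8 deletion alone (list means -0.35 and 0.02 against floxed controls). So was a matching rise of 1 immune type, as no list of 6 rose by more than 0.0254 of the interferon change in all 3 groups. No Mlkl-/- mice with intact FADD and CASP8 were measured. MLKL loss, alone or with deletion, double deletion, rare or other immune cells and the colony or its microbes stay open.

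The clock list was called between CASP8 IEC-KO Mlkl-/- and Casp8 fl/fl, but not with an estimated correlation (0.301), and of the 9 genes of the clock index only Nr1d1 passed (adjusted p = 9.29e-04). All 9 estimates, 8 of them of genes that did not pass, had the sign of a single phase shift, as a different time of collection would give. The series of title numbers could also differ in time, but within numbers under 100 the index difference was still 0.804 of that in all mice (-1.60 against -1.99, exact permutation p = 0.0286 and 0.0079). Those numbers were 36 to 40 against 63 to 84, so an effect of order or session within this series cannot be told apart from genotype. A shift of the clock in the mice themselves would look the same as a different time of collection, and no such time was given. With the clock index as a covariate, 103 genes of this comparison passed in place of 212.

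CASP8 IEC-KO replicate 1 had Casp8 and alpha-defensins nearer to the controls than its group (Casp8 10.89 against 9.63 to 10.57; defensin score -0.29 against -4.40 to -1.94). A floxed control under a wrong label might explain this, but its Casp8 lay 3.91 control SD below the lowest Casp8 fl/fl mouse. More non-epithelial tissue could add undeleted cells, but its enterocyte score exceeded the highest of the other 4 mice by 0.277; this test replaced an earlier one, also run, in which the mouse was highest of its group in 3 of 6 non-epithelial lists and lowest in 2. Incomplete deletion was not tested and stays open.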

How the results depend on the processing

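Of the tests and settings below, the clock index, the fit without both replicates 1, the correlation without Paneth cell genes and the left-out mice of scores and correlation were chosen only after the results had been seen. Comparisons are lettered in the order of the report: A FADD loss, B CASP8 loss, C and D MLKL loss without FADD and without CASP8, E ZBP1 loss, F RIPK3 loss, G and H triple mutants against FADD IEC-KO Mlkl-/- and CASP8 IEC-KO Mlkl-/-; against floxed controls, I FADD IEC-KO Mlkl-/-, J CASP8 IEC-KO Mlkl-/-, K FADD IEC-KO Zbp1-/-, L FADD IEC-KO RIPK3 IEC-KO and M triple mutants; N and O Zbp1-/- and RIPK3 IEC-KO against FADD IEC-KO Mlkl-/-; P the controls; Q and R the interactions of FADD with CASP8 loss and of MLKL loss.

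Of 705 calls of named genes, 287 held their direction and side of the threshold in every setting and 329 in every setting that left out no mouse; 2 reversed, Arntl (0.12) and Ciart (-0.0665) in H with the clock index as a covariate, which is built from them among others. Fits of only the groups compared lost 278 of these calls, title series 107, clock index 95, a fit without the triple mutants 64, sex index 42, quantile normalization 31, centring 29, array weights 27, trend and robust estimation 25, no replicates 1 19 and all probes 8. Of 241 list calls, 222 were lost with an estimated correlation and 133 with fry. Groups of 5, an unrecorded sex and collection time, and title series that overlap with genotype limit these results; dim genes were not excluded from the tests, and the probe summarization by the authors was not known. No paired analysis was possible because the labels pair no mice between groups.

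Leaving out single mice gave these lowest and highest counts: A 309 and 1090, B 204 and 1354, C 205 and 350, D 392 and 721, E 239 and 1041, F 53 and 667, G 935 and 1576, H 317 and 635, I 1220 and 1926, J 123 and 274, K 1507 and 2421, L 81 and 454, M 368 and 727, N 467 and 1019, O 442 and 1029, P 0 and 63, Q 0 and 10, R 7 and 25. Scores of CASP8-loss genes ranged from 1.49 to 2.01 in A, -0.76 to -0.47 in C, 0.20 to 0.51 in E, -1.35 to -1.05 in F, -1.16 to -0.78 in G, 0.89 to 1.48 in I, 1.69 to 2.48 in K, 0.45 to 0.76 in L and 0.11 to 0.32 for triple mutants against Fadd fl/fl; those of FADD-loss genes from 1.11 to 1.60 in B, -1.32 to -0.83 in D, -0.12 to -0.02 in H and 0.18 to 0.32 in J. The correlation ranged from 0.51 to 0.65. The interferon score, near 0 in B (0.02, at most 0.0805) and L (0.01), changed sign: in B to -0.0573, -0.0013 and -0.0241 without CASP8 IEC-KO replicate 3 and Casp8 fl/fl replicates 1 and 3, in L to -0.0167, -0.0024, -0.1008, -0.0426 and -0.0618 without FADD IEC-KO RIPK3 IEC-KO replicates 1, 2 and 3 and Fadd fl/fl replicates 4 and 5. These settings have fewer samples.

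Stricter thresholds left fewer genes by construction. At least 2-fold: A 91, B 58, C 80, D 132, E 12, F 64, G 94, H 26, I 174, J 49, K 144, L 19, M 38, N 81, O 133, R 4. Adjusted p under 0.01: A 192, B 189, C 161, D 278, E 135, F 44, G 611, H 206, I 927, J 101, K 1077, L 76, M 213, N 284, O 357, P 0, R 6. Fits of only the groups compared, with fewer samples and only their own spread, called A 153, B 10, C 145, E 0, F 19, K 820, L 64, M 451, N 323 and P 2 genes, and 9 lists in H. In these fits 3 of 44 named calls held in B and 0 of 33 in E, but 57 of 60 in G and 70 of 79 in I. All 4 have 5 mice per group, so the number of samples does not set them apart.

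In the following the cause was not tested. Without dim genes: A 1152, B 1284, E 1001, J 339, L 432, P 9, Q 15, R 21. Array weights: C 497, D 1083, E 337, F 488, G 2839, H 1479, J 524, M 1192, O 1456, P 15, Q 11, R 56. Title series: E 998, G 667, H 164, M 475, P 0, and 6 lists in Q. Sex index: F 126, P 8. Quantile normalization: P 11, Q 4. Trend and robust estimation: P 9, Q 6. All probes: P 0. Clock index: B 1392, D 901, F 46, H 322, J 103, O 580, P 0, Q 4. No replicates 1: B 1338, Q 2. Lists with an estimated correlation: A 2, B 2, C 1, D 3, E 0, F 0, G 0, H 0, I 2, J 1, K 2, L 3, M 1, N 0, O 2, Q 0, R 0. Lists by fry: B 11, C 5, D 12, E 1, F 5, H 2, J 2, L 6, M 5, N 7, Q 0, R 0. Scores of CASP8-loss genes chosen without a minimum fold change were -0.11 in C and 0.0211 for triple mutants against Fadd fl/fl, which was 0.15 with the title series removed. The correlation was 0.85 over called genes, 0.73 over bright genes, 0.55 without the Paneth cell lists and 0.53 without any further Defa, Mptx or Ang gene.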

Other observations

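The tests of random groupings and of genes near the targeted loci were fixed before the results were seen; the other values of this part were picked afterwards.

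Endothelial genes were lower in FADD IEC-KO Mlkl-/- than in Fadd fl/fl, with 6 of 10 called, Eng (-1.04 ± 0.21), Tek (-0.81 ± 0.19) and Kdr (-0.81 ± 0.20) most, and in FADD IEC-KO Zbp1-/-, where 7 of 10 fell and 1 rose, with Eng at -1.07 ± 0.21, Kdr at -0.97 ± 0.20 and Cdh5 at -0.90 ± 0.20 (5 mice per group; list adjusted p = 0.176 and 0.246 with an estimated correlation). Unfolded protein response genes rose in 6 of 17 in FADD IEC-KO Mlkl-/- against Fadd fl/fl, with Creld2 at 0.71 ± 0.14, Pdia6 at 0.49 ± 0.11 and Hyou1 at 0.39 ± 0.11 (0.447).

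Flanking sequence of another strain may travel with an altered locus, mutated or floxed, which predicts called genes near that locus. Within 10 Mb of Mlkl, 1 called gene lay in the FADD comparison (3.04 expected, Fisher's exact p = 0.379) and 4 in the CASP8 comparison (5.27 expected, exact p = 0.823), and near Ripk3 5 (4.12 expected, exact p = 0.612). Near Zbp1 15 of 648 called genes lay where 7.65 were expected (exact p = 0.0139, adjusted 0.0554), so some of these changes could come from flanking sequence.

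Random groupings of the same arrays were compared with the real grouping, 100 of each, the real included. In 16 comparisons only 1 grouping, the real, gave as many genes. The real count and the highest other were 727 and 108 for FADD loss, 813 and 696 for CASP8 loss, 313 and 68 for MLKL loss without FADD, 541 and 195 for MLKL loss without CASP8, 648 and 572 for ZBP1 loss, 303 and 15 for RIPK3 loss, and 1533 and 14, 605 and 4 for the triple mutants against FADD IEC-KO Mlkl-/- and CASP8 IEC-KO Mlkl-/-. Against floxed controls they were 2040 and 150 for FADD IEC-KO Mlkl-/-, 212 and 34 for CASP8 IEC-KO Mlkl-/-, 2313 and 1438 for FADD IEC-KO Zbp1-/-, 239 and 131 for FADD IEC-KO RIPK3 IEC-KO and 720 and 25 for the triple mutants; they were 804 and 96 for Zbp1-/- and 966 and 67 for RIPK3 IEC-KO against FADD IEC-KO Mlkl-/-, and 11 and 1 for the interaction of MLKL loss. Chance could not be excluded for the control groups (14 of 100 groupings had 1 gene or more, at most 171); what the groupings with high counts share was not tested. For the interaction of FADD and CASP8 loss the real count was 0, which all 100 of 100 groupings reach by construction (at most 45), so this decides nothing.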
